A study of Mus musculus with 6 samples.

How the data were processed

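The values analysed were made before deposit, and the steps named here are those the authors state. RNA was isolated with a column kit for small samples, cDNA was made with NuGEN Ovation V2, libraries were built with KAPA LTP, and reads were aligned with Bowtie2 (version not stated) to the mouse assembly mm10. The expected counts, as deposited, are the reads that RSEM 1.3.0 estimated for each RefSeq gene, with reads that match several genes shared among them. The TPM values, as deposited, are transcripts per 1e6 that RSEM computed from the expected count and the effective length of the same file. The effective length, per the file headers a column of the same RSEM output, is the transcript length minus 49 bases weighted over isoforms, which implies reads of 50 bases. Strandedness and the markers used to sort the cells are not stated in the labels. Genes were identified by the symbols in the files, and coordinates come from a mouse annotation of GRCm38, the assembly also named mm10.

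Expected counts were rounded to whole numbers. Genes were kept by filterByExpr with the groups given, which left 14448 of 24411. The test was the quasi-likelihood F test of edgeR 4.0.16 (glmQLFit and glmQLFTest) on all 6 libraries with TMM scaling and 5 groups, run in R 4.3.3 with limma 3.58.1, DESeq2 1.42.0 and the data.table package (1.17.8). All adjusted p values in the report are those of edgeR, by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. Where an adjusted p is given without an intestinal replicate, edgeR was fitted to the other libraries with the dispersions of the whole fit carried over. The fit has 1 residual degree of freedom, which comes from the intestinal pair. Printed fold changes are differences of log2 CPM with a prior count of 2, standard errors are approximations from the fitted dispersion, and ranges on single levels and ratios are 95% Poisson or binomial intervals that cover counting error only. A gene at 0 counts in a group was set to 3 counts over that group, and its fold is given as at least that size. Genes differing by size had a fold of at least 4 and 10 CPM or more in the higher group.

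The pair was checked first: the intestinal libraries differed by more than counting error (chi-square over its degrees of freedom 50.1 in 10691 genes), with a common dispersion of 0.39 and a biological coefficient of variation of 0.624. Its median was 0.88 for genes under 10 CPM, 0.54 for 10 to 100 CPM and 0.35 over 100 CPM. The test was tested on simulated data with the depths of these libraries and changes put into 150 genes per fold over 3 draws. For IL-33 lung against naive lung it recovered 5.3%, 28.7%, 48% and 68% of changes of 4, 8, 16 and 32-fold, with 3.4% false calls. For naive intestine against naive lung it recovered 10.7%, 36%, 62% and 82%, with 4% false calls. Where the simulated spread differed between genes, it recovered 2.7%, 18%, 38.7% and 56% for the first comparison and 5.3%, 33.3%, 61.3% and 79.3% for the second, with 26.4% and 18.2% false calls.

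The 24 gene lists were of S1P sensing and egress, homing, ILC2 identity, effectors, cytokine receptors, ILC3 and type 17 genes, ILC1 and natural killer genes, cell cycle, glycolysis, cholesterol synthesis, interferon response, costimulatory and checkpoint receptors, neuropeptide and lipid receptors, immediate early and stress genes, tissue residency, 8 kinds of other cells, and sex-linked genes. They hold 481 symbols, of which 479 were in the files, 5 through a synonym. List medians were placed among 10000 random lists matched on mean expression, as a description of these libraries. Tests of gene sets that need a correlation between genes were not used, since 1 residual degree of freedom cannot give it.

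Groups, comparisons, tests, thresholds, gene lists, the rule for named genes and the alternatives not named below as later choices were set before the data were examined. By that rule, each comparison names from the 10 largest changes in each direction among called genes with 10 CPM or more and the same sign against every library, from up to 4 members of each list with the largest change and 2 with the highest expression among those called (or, with none called, of 4-fold size), and 27 fixed genes of egress, homing, identity and function, of which 2 are not reported here. Predicted gene models, immunoglobulin and T cell receptor segments and pseudogenes were left out. Il6, Il2rb, E2f1 and Prdm1 are named outside the rule in places where 1 or 2 members of a list passed, and were chosen after their values were seen, as were the ratios of S1pr1 to Cdh5. The alternatives were RLE scaling, no filter, a filter at 10 CPM, DESeq2, limma-trend, assumed coefficients of variation of 0.4 and 0.2, an offset for effective length, only the 2 groups compared, TPM with a pseudocount of 1, a prior count of 0.5, and values without each intestinal library. Chosen after seeing the data were tests without each intestinal library and the position of libraries over the genes these call. Ribosomal RNA reads (Rn45s) were kept, at 3.19% and 2.89% of counts in IL-25 lung and the node and 0.238% to 0.961% elsewhere. The bone marrow groups of the study are not analysed here.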

Results

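RNA was measured by bulk sequencing in group 2 innate lymphoid cells (ILC2s), lymphocytes without antigen receptors that release interleukin-5 and interleukin-13, from C57BL/6 mice. The 6 libraries fell into 5 groups: lung of naive mice (1 library), lung of mice given IL-33 into the nose on 3 successive days (1), lung of mice given IL-25 into the peritoneum on 3 successive days (1), mesenteric lymph node of mice given the same IL-25 course (1), and intestine of naive mice (2). IL-33 and IL-25 are alarmins, cytokines that epithelia release and that activate ILC2s. The labels name the IL-25 lung cells inflammatory ILC2s and the naive and IL-33 lung cells nILC2, so IL-25 and cell label cannot be separated. The series is about movement of inflammatory ILC2s between organs through sphingosine 1-phosphate (S1P), the lipid that draws lymphocytes out of tissues.

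Total expected counts were 6018433 for naive lung, 5550653 for IL-33 lung, 8229919 for IL-25 lung, 7547819 for the lymph node, 4235217 for intestinal replicate 1 and 2772801 for intestinal replicate 2. Genes with a count numbered 15154, 13679, 16249, 15613, 14130 and 13506 in the same order. A count of 0 allows up to 0.443, 0.604, 0.333, 0.35, 0.79 and 1.21 counts per 1e6 (CPM), set at 3 counts and covering counting error only. In all, 14448 of 24411 genes were tested. Each fold change is a log2 difference in CPM, with the fitted standard error after the ± sign. That error hardly reflects a gene's own replicate spread, and intestinal levels are the mean ± SD of 2 libraries. Where the levels of a gene are joined by "and" rather than "against", the difference did not pass. Counts for a gene list are given over all genes, then adjusted over the list alone.

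The only replicates were the 2 intestinal libraries, so the spread of every other group was assumed to match theirs, and differences among the 4 lone libraries have no replicate check. The 2 intestinal libraries differed by more than 2-fold in 30.4% of 7866 genes with 10 CPM or more. The limma-trend test called 0 genes in each of the 7 comparisons, where 657 to 1971 of 14448 genes had an unadjusted p under 0.05 in the 4 comparisons without intestine, and 1169 to 2026 in the 3 with it. All calls given here are those of edgeR at an adjusted p of 0.05.

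Transcripts of other cell types differed between libraries. Markers of macrophages, monocytes and dendritic cells summed to 13100 CPM in IL-33 lung, 2770 in IL-25 lung, 862 in naive lung, 70 in the node, and 155 and 106 in the intestinal replicates 1 and 2. Markers of stroma and endothelium summed to 987 CPM in IL-25 lung and 661 in IL-33 lung, against 67.3 in naive lung, 153 in the node, and 156 and 258 in the intestine. In the node, markers of T cells summed to 604 CPM and markers of B and plasma cells to 616. IL-33 lung held 731 and 316 CPM of these, and naive lung 229 and 82. Intestinal epithelial markers summed to 3950 CPM in intestinal replicate 2 and 55.3 in replicate 1, and lung epithelial markers to between 17 and 136 CPM in all 6 libraries. Granulocyte and mast cell markers ranged from 13.9 CPM in the node to 491 in IL-33 lung, and erythroid and platelet markers from 6.32 to 33.8 CPM.

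**Figure D1:**
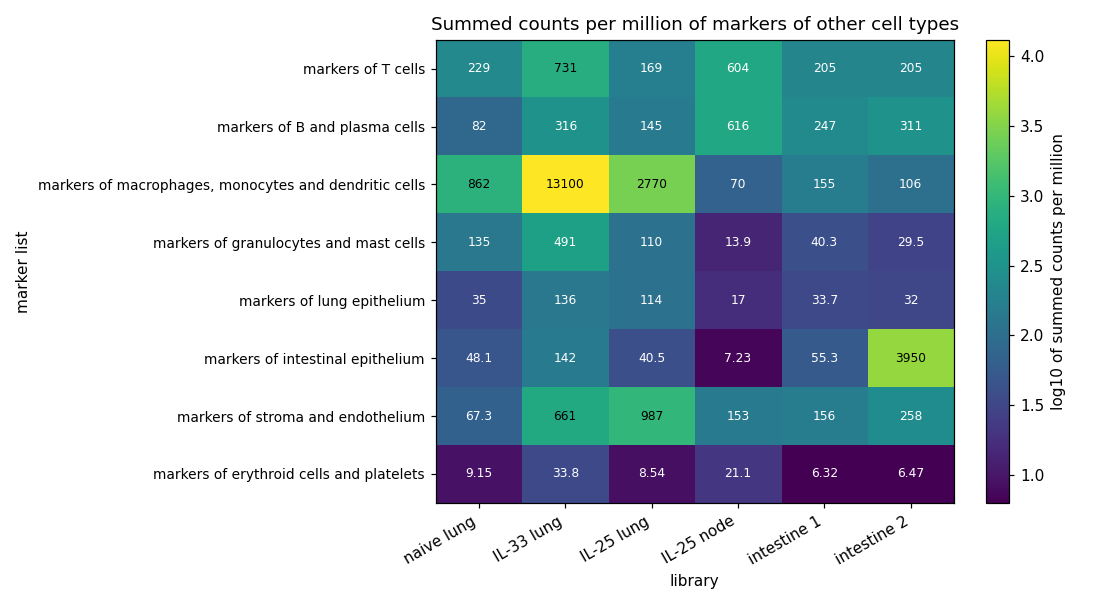
Summed expression (CPM, log axis) of 8 lists of marker genes for other cell types in each of the 6 libraries. Macrophage markers reached 13100 CPM in IL-33 lung and intestinal epithelial markers 3950 CPM in intestinal replicate 2.

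The libraries most alike were IL-25 lung and the lymph node. Across 14448 genes their log2 CPM had a root mean square difference of 1.17, a Pearson r of 0.906 and a Spearman rho of 0.917. For the 2 intestinal libraries the values were 1.71, 0.833 and 0.84, and for naive lung and intestinal replicate 1 they were 1.39, 0.883 and 0.894. These correlations run across genes, which are not independent replicates.

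In the lung, IL-33 treatment went with higher RNA of some cytokine and cell division genes. Il9, an interleukin of type 2 immunity, was at 516 CPM in IL-33 lung against 0.591 in naive lung (log2 fold change 9.12 ± 0.94, adjusted p = 8.98e-13). Il13, which drives mucus production, rose from 20.8 to 171 CPM (3.02 ± 0.57, adjusted p = 0.00039), and Areg, an epidermal growth factor receptor ligand for tissue repair, from 200 to 1320 (2.72 ± 0.56, adjusted p = 0.00219). The proliferation marker Mki67 rose from 91.1 to 923 CPM (3.34 ± 0.51, adjusted p = 3.34e-06). This comparison asks what IL-33 changes in lung ILC2s.

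Of 24 effector genes tested, 3 rose (Il9, Il13 and Areg), 0 fell and 21 did not pass, and 6 rose over the list alone. Il5, which sustains eosinophils, was at 365 and 162 CPM and was not called (1.18 ± 0.54, adjusted p = 0.455). Among 40 cell cycle genes, 6 rose, 0 fell and 34 did not pass, with 7 higher over the list alone. They included the cyclin Ccne2 (4.74 ± 1.27), the kinetochore motor Cenpe (3 ± 0.62) and the replication clamp Pcna (2.29 ± 0.62). Of 24 costimulatory and checkpoint receptors, 1 rose, the checkpoint receptor Ctla4 (2.81 ± 0.56, adjusted p = 0.00112), and 1 was higher and 1 lower over the list alone. Itga1, an integrin chain of tissue-resident lymphocytes, was the 1 called gene of both the 29 homing genes and the 15 tissue residency genes, at 184 against 1.62 CPM (6.55 ± 1.04, adjusted p = 6.57e-05). Over the list alone, 1 homing gene was higher, and 1 residency gene was higher and 1 lower.

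None of 26 ILC2 identity genes was called by edgeR, over all genes or over the list alone, among them Gata3 (-0.97 ± 0.54), the IL-33 receptor gene Il1rl1 (-0.59 ± 0.52) and Klrg1 (-0.24 ± 0.65). Of 25 cytokine receptor genes 0 were called, and 1 was higher over the list alone. Srebf2, a regulator of sterol synthesis, was the 1 called gene of 22 in cholesterol synthesis and was lower (-2.90 ± 0.75, adjusted p = 0.0262), and over the list alone 1 was higher and 2 lower. Oasl2 was the 1 interferon response gene of 25 to rise (3.81 ± 0.93, adjusted p = 0.0262), with 2 higher over the list alone. Ramp3, a subunit of adrenomedullin and calcitonin-like receptors, was the 1 called gene of 19 neuropeptide and lipid receptors, at 0 counts in IL-33 lung against 12 CPM in naive lung, at least 19.8-fold lower. Of 19 ILC3 and type 17 genes, 22 glycolysis genes and 30 immediate early and stress genes, 0 were called. Over each list alone, the first 2 lists had 0 calls and the last had 2 higher and 4 lower. Of 22 ILC1 and natural killer genes 0 were called and 1 was higher over the list alone.

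S1pr1, the S1P receptor through which lymphocytes leave tissues, was the 1 called gene of 21 in S1P sensing and egress, at 79.4 CPM in IL-33 lung against 8.42 in naive lung (3.19 ± 0.76, adjusted p = 0.0138), and 1 was higher over the list alone. The endothelial cadherin Cdh5 was at 175 against 11.1 CPM in the same libraries (3.94 ± 0.83, adjusted p = 0.00448), and the lymphatic endothelial receptor Lyve1 at 331 against 5.17 (5.91 ± 0.79, adjusted p = 1.06e-06). The ratio of S1pr1 to Cdh5 was 0.454 in IL-33 lung and 0.76 in naive lung. S1pr4, an S1P receptor of blood cells, was at 5.84 and 10.9 CPM and was not called (-0.87 ± 1.04). The CD69 gene, whose product holds S1pr1 inside the cell, was at 435 and 250 CPM (0.80 ± 0.59), and Klf2, a driver of S1pr1 transcription, at 0.806 and 3.84 (-1.87 ± 1.44).

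Markers of other cell types moved alongside these genes. Of 16 macrophage and dendritic cell markers, 2 rose: Chil3, a chitinase-like protein of alveolar macrophages, was at 10800 against 316 CPM (5.09 ± 0.50, adjusted p = 2.04e-13), and the mannose receptor Mrc1 rose by 3.03 ± 0.67. Over the list alone, 7 of these markers were higher. Cd3e, a T cell receptor subunit, was the 1 called T cell marker of 15 (2.95 ± 0.69, adjusted p = 0.0116), and Blnk the 1 called B cell marker of 13 (6.07 ± 1.16, adjusted p = 0.00246), with the same counts over each list alone. Of 15 markers of stroma and endothelium 2 rose, Cdh5 and Lyve1, also over the list alone. Of 11 granulocyte and mast cell markers, 8 lung epithelial, 18 intestinal epithelial, 4 erythroid or platelet and 3 sex-linked genes, 0 were called over all genes, and 2 granulocyte markers were higher over the list alone.

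Over all genes, edgeR called 134 higher and 29 lower in IL-33 lung, and 1376 genes had an unadjusted p under 0.05. With an assumed coefficient of variation of 0.4 the calls were 1059 higher and 1540 lower. Outside the lists, the largest called rises in IL-33 lung, from ILC2s or other cells, included the neuronal adhesion gene Flrt3, at 51.2 CPM with 1 count in naive lung (95% counting interval of the ratio 61.6 to 13700), the mitotic gene Depdc1a (6.49 ± 1.21), the adhesion molecule Mcam (6.44 ± 1.45), Sparcl1 (at least 85.1-fold), Rapgef5 (at least 110-fold) and the phosphate transporter of alveolar epithelium Slc34a2 (at least 57.8-fold). Lower in IL-33 lung were Rnf185, a ubiquitin ligase (at least 28.1-fold lower), Dlg4 (3 counts, ratio interval 0.00274 to 0.0395), the linear ubiquitin ligase subunit Rbck1 (-4.93 ± 1.28) and the kinase Cdk16 (-4.72 ± 1.23). By size alone, at 4-fold or more and 10 CPM or more, 886 genes were higher and 732 lower. With at least 10 CPM in some library required, 18 genes were called, all higher. Most of the 134 higher genes and all lower ones lost their call.

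IL-25 lung ILC2s were set against naive lung ILC2s to ask how inflammatory ILC2s differ from resident ones. They held more of the gut-homing receptor gene Ccr9, at 2180 against 76.6 CPM (4.82 ± 0.53, adjusted p = 1.43e-11), and less of Il1rl1, at 74.8 against 2950 (-5.30 ± 0.52, adjusted p = 6.72e-14). Klrg1, an inhibitory receptor that marks inflammatory ILC2s, rose from 56.3 to 343 CPM (2.6 ± 0.64, adjusted p = 0.00908). Il13 rose from 20.8 to 1050 CPM (5.63 ± 0.57, adjusted p = 7.31e-13), while Il5 fell from 162 to 33.5 (-2.26 ± 0.55, adjusted p = 0.00585). Mki67 was at 3500 against 91.1 CPM (5.26 ± 0.51, adjusted p = 1.97e-14).

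Cell division genes rose: of 40 tested, 21 rose, 0 fell and 19 did not pass, and 34 were higher over the list alone. The median log2 fold change of the list was 3.82, and Rrm2, a ribonucleotide reductase subunit (6.12 ± 0.71), the topoisomerase Top2a (4.77 ± 0.58) and the spindle checkpoint kinase Bub1b (5.63 ± 1.03) were among them. Of 22 glycolysis genes, 3 rose and 0 fell, namely Pkm (2.82 ± 0.63), Gapdh (2.75 ± 0.51) and Aldoa (2.51 ± 0.71), with 5 higher over the list alone. In cholesterol synthesis 0 of 22 genes were called, over all genes or over the list alone, at a median of 1.35 that lay above all 10000 random lists of like expression.

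The ILC2 identity list had 1 gene higher (Klrg1), 6 lower and 19 not passed, and over the list alone 1 higher and 9 lower. Besides Il1rl1, those lower included the IL-7 and IL-2 receptor chains Il7r (-3.44 ± 0.51) and Il2ra (-3.79 ± 0.52). The others were Kit (-2.46 ± 0.54), Cd200r1 (-3.33 ± 0.75) and Arg1, an arginase of ILC2s (-3.01 ± 0.54). Il17rb, a subunit of the IL-25 receptor, was at 208 and 201 CPM (0.05 ± 0.55), Gata3 at 220 and 504 (-1.19 ± 0.54), and Rora at 729 and 1770 (-1.28 ± 0.50). Thy1 was at 163 and 212 CPM (-0.38 ± 0.70). Of 25 cytokine receptors, 2 rose and 4 fell, with 2 and 5 over the list alone. Il2rb, the IL-2 receptor beta chain (2.29 ± 0.56), and the tumour necrosis factor receptor Tnfrsf1b (2.37 ± 0.60) rose.

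Among 24 effector genes, 2 rose and 8 fell, also over the list alone. Il6 rose with Il13 (4.16 ± 0.95), and Lif, a cytokine of the same family as Il6, fell with Il5 (-3.05 ± 0.58). Il2 fell to 2 counts from 48.7 CPM (95% counting interval of the ratio 0.000549 to 0.0166), the chemokine gene Ccl1 to 1 count from 31.9 (8.76e-05 to 0.0196) and Tnfsf14, the gene of LIGHT, to 1 count from 22.7 (0.000123 to 0.0276). Areg was at 109 and 200 CPM and was not called (-0.87 ± 0.56). The costimulatory and checkpoint receptors had 2 genes higher and 6 lower of 24, with 5 and 7 over the list alone. Ctla4 rose 120-fold, from 18 to 2200 CPM (6.91 ± 0.56, adjusted p = 4.75e-18), and the ligand Icosl (-3.96 ± 0.90), the glucocorticoid-induced receptor gene Tnfrsf18 (-3.77 ± 0.83) and Cd226 (-3.70 ± 0.87) fell.

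Of 29 homing genes, 3 rose and 2 fell, with 4 and 3 over the list alone. Ccr9, Itga1 (4.28 ± 1.04) and the integrin chain Itga4, a part of the gut-homing integrin (1.87 ± 0.49), rose, and the chemokine receptors Ccr2 (-4.20 ± 0.58) and Ccr8 (-4.21 ± 0.70) fell. Itgb7, the partner chain of Itga4, was at 378 and 141 CPM (1.42 ± 0.63), and Cxcr6 at 107 and 170 (-0.66 ± 0.59). Of 15 tissue residency genes, 2 rose and 4 fell, with the same counts over the list alone. The transcription factor Prdm1 rose (5.15 ± 0.64), and the G protein regulator Rgs2 (-2.85 ± 0.51), the phosphatase Inpp4b (-3.80 ± 0.52) and the lysophosphatidylserine receptor Gpr34 (-5.12 ± 1.21) fell.

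In the list of S1P sensing and egress, 2 of 21 genes rose and 0 fell, with 6 higher over the list alone. S1pr1 was at 225 against 8.42 CPM (4.69 ± 0.76, adjusted p = 1.78e-05), and the G protein subunit Gnai2, through which S1pr1 signals, rose as well (2.16 ± 0.60). Endothelial genes moved with S1pr1: Cdh5 was at 249 against 11.1 CPM (4.45 ± 0.82, adjusted p = 0.000334), the clotting factor gene Vwf at 214 against 2.36 (6.31 ± 1.06, adjusted p = 0.000113), and the ratio of S1pr1 to Cdh5 was 0.902 against 0.76. S1pr4 was at 107 and 10.9 CPM and was not called (3.25 ± 1.01, adjusted p = 0.0789). Klf2 was at 35.2 and 3.84 CPM (3.09 ± 1.3), Cd69 at 430 and 250 (0.78 ± 0.59), and S1pr5 at 0.776 and 2.66 (-1.43 ± 3.47).

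Of 19 ILC3 and type 17 genes, 2 rose and 0 fell, also over the list alone: the transcription factors Irf4 (3.21 ± 0.61) and Batf (4.71 ± 1.05). Il17a was at 27.7 CPM and 2 counts in naive lung (95% counting interval of the ratio 25.7 to 780) and was not called (5.47 ± 2.05), and Il22 had 0 counts in all 4 libraries other than the intestinal ones. Of 22 ILC1 and natural killer genes 1 rose, the granzyme Gzma (5.13 ± 1.26), and 1 was higher and 1 lower over the list alone. Of 25 interferon response genes 1 rose, Gbp3 (3.86 ± 0.92), with the same count over the list alone. The neuropeptide and lipid receptors had 4 genes lower of 19 and 0 higher, also over the list alone, among them Vipr2, a receptor of vasoactive intestinal peptide (-4.41 ± 0.65), the calcitonin gene-related peptide receptor subunit Ramp1 (-5.73 ± 1.33) and the lipoxygenase Alox5 (-4.04 ± 0.77). Of 30 immediate early and stress genes 3 fell and 0 rose, Fosb (-3.26 ± 0.51), Egr3 (-3.17 ± 0.87) and Nr4a3 (-2.70 ± 0.51), with 1 higher and 3 lower over the list alone.

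Stromal and endothelial markers had 5 of 15 genes higher, also over the list alone, including Pecam1 (2.51 ± 0.72) and Lyve1 (5.13 ± 0.79). Chil3 was the 1 called macrophage marker of 16 and rose (2.33 ± 0.50), Cd79b, a B cell receptor subunit, was the 1 of 13 B cell markers to rise, from 1 count to 74.9 CPM (95% counting interval of the ratio 90.7 to 20100), and the mast cell protease Cpa3 was the 1 of 11 granulocyte and mast cell markers to fall (-5.55 ± 1.47), with the same counts over each list alone. Of T cell markers (15), lung epithelial (8), intestinal epithelial (18), erythroid or platelet (4) and sex-linked genes (3), 0 were called, and 1 lung epithelial marker was higher over the list alone.

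In total 248 genes were higher and 161 lower in IL-25 lung, and 1328 had an unadjusted p under 0.05. The largest called differences included Tnfrsf8, which encodes CD30 (at least 144-fold higher), the Notch pathway ligase Dtx1 (at least 137-fold higher), the mitotic kinesin Kif18b (at least 157-fold higher) and the transcription factor Tox2 (1 count in naive lung, ratio interval 139 to 30600). On the lower side stood the scavenger receptor Stab2, at 19.7 against 2350 CPM (-6.87 ± 0.54), the contactin Cntn1 (-6.72 ± 0.71), the lysophospholipid acyltransferase Lpcat2 (-7.06 ± 0.73), the scaffold gene Shank2 (at least 241-fold lower) and the secreted glycoprotein Stc2 (at least 181-fold lower). By size alone, 855 genes were higher and 473 lower. With at least 10 CPM in some library required, 166 genes were called.

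**Figure D2:**
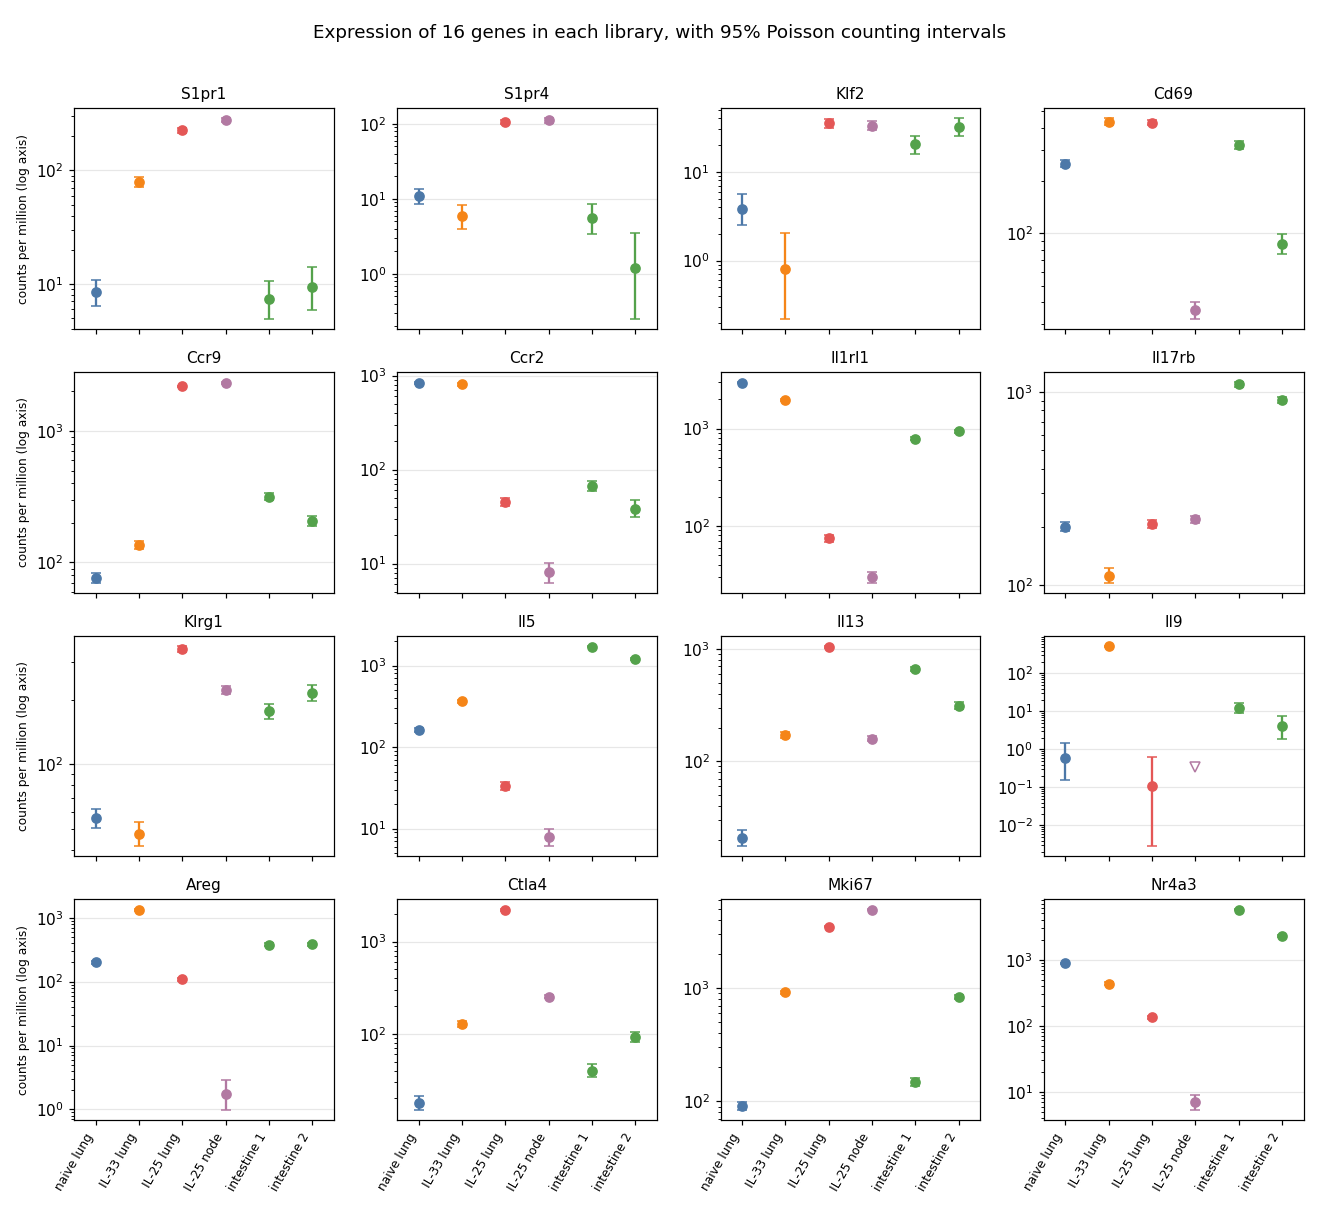
Expression (CPM, log axis) of 16 genes of S1P sensing, homing, identity, effector function and activation in each of the 6 libraries, with 95% Poisson intervals as bars and open triangles for 0 counts, drawn at the level of 3 counts. Ccr9 was at 2180 CPM in IL-25 lung and 2310 in the lymph node, against 76.6 in naive lung.

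The 2 treated lung libraries, which differ in cell label too, were compared, since both cytokines activate ILC2s. IL-25 lung held more Ccr9 than IL-33 lung (4 ± 0.53, adjusted p = 2.44e-08), more Klrg1 (2.84 ± 0.64, adjusted p = 0.00299) and more Il13 (2.61 ± 0.56, adjusted p = 0.00137). Il9, at 516 CPM in IL-33 lung, had 1 count in IL-25 lung (95% counting interval of the ratio 5.44e-06 to 0.0012, adjusted p = 2.39e-15). Areg (-3.59 ± 0.56, adjusted p = 3.53e-06), Il5 (-3.43 ± 0.55, adjusted p = 3.72e-06), Arg1 (-4.29 ± 0.54, adjusted p = 4.09e-09) and Il1rl1 (-4.71 ± 0.52, adjusted p = 2.15e-11) were lower in IL-25 lung.

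Of 24 effector genes, 1 was higher in IL-25 lung, 10 were lower and 13 did not pass, with 1 and 10 also over the list alone, at a median of -1.68. Csf2, the gene of granulocyte-macrophage colony-stimulating factor (-6.19 ± 0.71), Il2 (2 counts, ratio interval 0.000208 to 0.00625) and Ccl1 (1 count, 7.66e-05 to 0.0172) were among those lower. Of 40 cell cycle genes 15 were higher and 1 lower, with 30 and 1 over the list alone. Mki67 (1.92 ± 0.50), Top2a (2.15 ± 0.58) and the mitotic kinase Aurkb (4.74 ± 1.25) were higher, and Stmn1, a microtubule regulator, had 3 counts in IL-33 lung against 60.6 CPM in IL-25 lung (95% counting interval of the ratio 34.1 to 487). The transcription factor E2f1 was the gene lower (-2.80 ± 0.71). Of 22 glycolysis genes 3 were higher, Pkm (3.42 ± 0.63), Gapdh (2.59 ± 0.51) and the lactate transporter Slc16a1 (4.57 ± 1.20), and of 22 cholesterol synthesis genes 2 were higher, Srebf2 (3.94 ± 0.74) and Dhcr7 (4.34 ± 1.31), with 0 lower in either and 3 higher in each over the list alone.

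S1P sensing and egress genes were higher in 5 of 21 cases and lower in 0, also over the list alone. They were S1pr4, at 107 against 5.84 CPM (4.12 ± 1.03, adjusted p = 0.0135), Klf2, at 35.2 against 0.806 (4.96 ± 1.41, adjusted p = 0.0292), Gnai2 (2.19 ± 0.60), the receptor kinase Adrbk1 (3.43 ± 0.80) and the membrane linker Msn (1.69 ± 0.50). S1pr1 was at 225 and 79.4 CPM and was not called (1.5 ± 0.74, adjusted p = 0.348). Cdh5 was at 249 and 175 CPM, and Vwf was higher in IL-25 lung (4 ± 1.02, adjusted p = 0.0181), the 1 called gene of 15 stromal and endothelial markers, also over the list alone. Of 29 homing genes 2 were higher and 1 lower, with 2 and 4 over the list alone: Ccr9, Itgb7 (2.61 ± 0.63) and, lower, Ccr2 (-4.16 ± 0.58). Itga4 was at 7020 and 4540 CPM (0.63 ± 0.49) and Cd69 at 430 and 435 (-0.02 ± 0.59).

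ILC2 identity genes were higher in 1 of 26 cases and lower in 5, with 2 and 8 over the list alone, and the lower ones included Il7r (-3.47 ± 0.51) and Il2ra (-3.85 ± 0.52). Il17rb was at 208 and 112 CPM (0.89 ± 0.56) and Gata3 at 220 and 256 (-0.22 ± 0.54). Of 25 cytokine receptors 2 were higher and 4 lower, with 3 and 8 over the list alone, and the IL-18 receptor chain Il18r1 was among the lower (-2.81 ± 0.64). Costimulatory and checkpoint receptors were higher in 3 of 24 cases and lower in 5, with 5 and 8 over the list alone: Ctla4 (4.10 ± 0.55) was higher, and Cd226 (-4.45 ± 0.87), Icosl (-4.07 ± 0.90) and Cd96 (-3.58 ± 0.63) were lower. Residency genes were higher in 1 of 15 cases (Prdm1, 3.46 ± 0.64) and lower in 3, among them Rgs2 (-3.60 ± 0.51) and Gpr34 (-6.68 ± 1.21), with 2 and 4 over the list alone.

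Of 19 neuropeptide and lipid receptors 1 was higher, the prostaglandin receptor Ptger1 (3.64 ± 1.01), and 3 were lower, among them Vipr2 (-4.20 ± 0.65), with 1 and 5 over the list alone. Immediate early and stress genes had 0 of 30 higher and 3 lower, Fosb (-1.68 ± 0.51), Atf3 (-2.23 ± 0.65) and Nr4a3 (-1.68 ± 0.51), with 1 and 4 over the list alone. Batf was higher in the type 17 list of 19 (3.59 ± 1.03), where 2 were higher over the list alone, and Ifi44 lower in the interferon list of 25 (-3.45 ± 0.88), with the same count over the list alone. Of 22 ILC1 and natural killer genes 0 were called, with 1 higher and 1 lower over the list alone.

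Markers of macrophages were lower in IL-25 lung for 3 of 16 genes, Chil3 (-2.76 ± 0.50, adjusted p = 6.77e-05), Mrc1 (-2.32 ± 0.66) and the complement gene C1qc (-5.12 ± 1.35), and Cd3e of 15 T cell markers was lower (-4.08 ± 0.69). Of 13 B cell markers Cd79b was higher (4.88 ± 1.17, 95% counting interval 18.8 to 68) and Blnk lower (-6.25 ± 1.15), and of 11 granulocyte and mast cell markers the eosinophil ribonuclease Ear1 (-3.43 ± 0.99) and Cpa3 (-6.57 ± 1.47) were lower. The counts over each of these lists alone were the same. Lung epithelial (8), intestinal epithelial (18), erythroid or platelet (4) and sex-linked genes (3) had 0 calls, and 1 sex-linked gene was lower over the list alone.

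In total 259 genes were higher and 264 lower in IL-25 lung (2527 and 1150 with an assumed coefficient of variation of 0.4), and 2034 had an unadjusted p under 0.05. Tnfrsf8 had 2 counts in IL-33 lung against 64 CPM in IL-25 lung (95% counting interval of the ratio 43.8 to 1310). Ahcy, an enzyme of methionine metabolism (at least 86.6-fold higher), the mitotic genes Cdca3 (at least 65.1-fold higher) and Spdl1 (at least 40.2-fold higher), the chemokine Cxcl13 (at least 346-fold lower), the purinergic receptor P2ry1 (-6.67 ± 1.35) and Lpcat2 (-6.84 ± 0.73) were among the largest called differences. By size alone, 1341 genes were higher and 956 lower. With at least 10 CPM in some library required, 263 genes were called.

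After IL-25, ILC2s of the mesenteric lymph node were compared with lung ones, to ask how cells of the same treatment differ between organs. The labels name the node cells ILC2s and the lung cells inflammatory ILC2s, so organ and cell label cannot be separated here. The node held less of the immediate early genes, which respond within minutes to activation or stress: Nr4a1 was at 9.68 against 597 CPM (-5.90 ± 0.55, adjusted p = 2.13e-15), Fosl2 at 14.5 against 426 (-4.85 ± 0.52, adjusted p = 1.53e-12) and Nr4a2 at 6.3 against 159 (-4.59 ± 0.57, adjusted p = 6.31e-10). Cd69 was at 36 against 430 CPM (-3.56 ± 0.59, adjusted p = 1.44e-05). Areg fell from 109 CPM in the lung to 1.75 in the node (-5.71 ± 0.63, adjusted p = 5.42e-13), and Il13 from 1050 to 159 (-2.72 ± 0.56, adjusted p = 0.000928).

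Of 30 immediate early and stress genes, 0 rose, 15 fell and 15 did not pass, and 21 were lower over the list alone, at a median of -2.42. The phosphatase Dusp1 (-4.41 ± 0.50), the transcription factor Klf6 (-2.10 ± 0.53) and Atf3 (3 counts, ratio interval 0.00137 to 0.0195) were among them. Of 24 effector genes 6 fell and 0 rose, with 7 lower over the list alone, including Il6 (-4.63 ± 0.95), Il5 (-2.05 ± 0.56) and the neuropeptide gene Calca (2 counts, ratio interval 0.00321 to 0.101). The list's median was -1.28, or -1.01 with the 1 gene at 0 set to its limit. Of 15 residency genes 5 fell, with 6 lower over the list alone, among them Rgs2 (-3.85 ± 0.51), Itga1 (-4.46 ± 1.04) and Cd69, and of 29 homing genes 2 fell, Itga1 and Ccr2 (-2.43 ± 0.60), also over the list alone. Ctla4 was the 1 checkpoint gene of 24 to fall, from 2200 to 254 CPM (-3.11 ± 0.55, adjusted p = 5.37e-05), and Calcrl, a neuropeptide receptor subunit that endothelium also expresses, the 1 of 19 in its list (-3.45 ± 0.58, adjusted p = 1.48e-05), with the same counts over each list alone.

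Few genes of movement and identity passed between the organs. S1pr1 was at 275 CPM in the node and 225 in the lung (0.29 ± 0.74, adjusted p = 1), while Cdh5 was at 3.27 against 249 CPM (-6.11 ± 0.85, adjusted p = 5.51e-07). S1pr4 was at 111 and 107 CPM (0.05 ± 0.99), Klf2 at 33 and 35.2 (-0.09 ± 1.27), and Ccr9 at 2310 and 2180 (0.09 ± 0.53). Cd69 was the 1 called gene of 21 in the S1P list, also over the list alone. Ccr7, a lymph node homing receptor, was at 44.4 and 7.99 CPM (2.43 ± 1.54). Of 26 identity genes 0 were called, and 1 was higher over the list alone. Klrg1 was at 221 and 343 CPM, Gata3 at 136 and 220, and Il1rl1 at 29.7 and 74.8.

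Of 40 cell cycle genes 0 were called, over all genes or over the list alone, and all 40 had a higher value in the node, at a median of 0.66. Of 25 cytokine receptors, 19 type 17 genes and 22 ILC1 and natural killer genes 0 were called, and 1, 1 and 2 were lower over the list alone. Glycolysis (22), cholesterol synthesis (22) and interferon response (25) had 0 calls, over all genes or over each list alone.

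Cells of other types differed between the 2 organs. Of 16 macrophage markers 4 were lower in the node, with 6 over the list alone: Chil3 was at 11.1 against 1590 CPM (-7.12 ± 0.51, adjusted p = 3.75e-23) and Lyz2 at 10.7 against 785 (-6.15 ± 0.59, adjusted p = 4.65e-14). Of 15 stromal and endothelial markers 4 were lower, with 5 over the list alone, such as Lyve1 (-7.90 ± 0.93) and Vwf (-8.06 ± 1.16), and of 11 granulocyte markers 2 were lower, Ear1 (-4.41 ± 1.12) and Ear2 (-5.43 ± 1.3), also over the list alone. Scgb1a1, a secretoglobin of airway epithelium, was the 1 lower of 8 lung epithelial markers (at least 110-fold lower), and Krt19 the 1 lower of 18 intestinal epithelial markers (-4.55 ± 1.07), each with 2 over the list alone. Cd3e rose in the node (2.93 ± 0.69, adjusted p = 0.00845) as the 1 called T cell marker of 15, also over the list alone. B cell markers had 0 of 13 called, over all genes or over the list alone, at a median of 3.08. Erythroid or platelet (4) and sex-linked genes (3) had 0 calls.

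In total 4 genes were higher and 156 lower in the node, and 513 had an unadjusted p under 0.05, fewer than chance alone would give. The 4 were Cd3e, the signalling adaptor Card6 (2.84 ± 0.79) and 2 genes, Rps27rt and Amd2, that have near-identical copies elsewhere, so their counts are uncertain. Among the largest falls were genes of lung endothelium, Ptprb (-8.25 ± 0.74), Adgrf5 (-8.36 ± 0.73) and the angiotensin-converting enzyme Ace (-7.69 ± 1.02), and Ptgs2, the inducible cyclooxygenase (-7.75 ± 0.75). By size alone, 58 genes were higher and 442 lower. With at least 10 CPM in some library, 1 higher and 88 lower passed.

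Naive intestinal and naive lung ILC2s were compared to ask how resident cells of the 2 tissues differ. Intestinal cells held more Il13, at 488 ± 248 against 20.8 CPM (4.43 ± 0.50, adjusted p = 3.14e-10), more Il5, at 1450 ± 356 against 162 (3.15 ± 0.47, adjusted p = 2.78e-06), and more Calca, at 709 ± 63.8 against 40 (4.13 ± 0.52, adjusted p = 4.7e-08). Il17rb was higher in the intestine, at 998 ± 131 against 201 CPM (2.31 ± 0.48, adjusted p = 0.00168), and Il1rl1 lower, at 863 ± 109 against 2950 (-1.78 ± 0.45, adjusted p = 0.00324, and -1.65, adjusted p = 0.0695 without intestinal replicate 1). Both intestinal libraries lay on the same side of naive lung for each of these genes. Heat shock genes were higher too (below), and dissociation stress was not tested. From here on, square brackets hold the values without intestinal replicates 1 and 2, in this order, where these moved a called fold by over 1.5 times (a bound or 95% counting interval of the ratio at 3 counts or fewer).

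Of 24 effector genes 8 were higher and 1 lower, with 9 and 1 over the list alone, and 5 and 7 were higher without intestinal replicates 1 and 2, with 0 lower in each case. Il6 was among those higher (4.22 ± 0.83 [3.31, 5.13]), and Il4, a cytokine of type 2 immunity, was at 152 ± 48.5 against 4.28 CPM (5.01 ± 0.82). Homing genes were higher in 3 of 29 cases and lower in 3, with 5 and 5 over the list alone. The chemokine receptor Ccr4 (3.43 ± 0.47) and Ccr9, at 263 ± 77 against 76.6 CPM (1.74 ± 0.46, and 1.44, adjusted p = 0.153 without replicate 1), were higher, and Ccr2 was lower (-4.02 ± 0.51). Without intestinal replicates 1 and 2, 2 homing genes were higher in each case, and 3 and 2 lower. Identity genes had 2 of 26 higher and 2 lower, with 6 and 2 over the list alone, Rora (1.72 ± 0.43) being the other gene higher. Thy1 was at 42.1 ± 25.8 against 212 CPM (-2.47 ± 0.61 [-3.13, -1.80], and adjusted p = 0.466 without replicate 2), and with either intestinal library left out 2 identity genes were higher and 1 was lower. Gata3 was at 1470 ± 153 and 504 CPM (1.54 ± 0.46, adjusted p = 0.0683), Cxcr6 at 566 ± 87.5 and 170 (1.73 ± 0.51), and Klrg1 at 195 ± 27.2 and 56.3 (1.78 ± 0.56).

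Type 17 genes were higher in 3 of 19 cases and lower in 0, with 4 higher over the list alone and 3 with either intestinal library left out. Il22, a cytokine that acts on epithelium, was at 40.9 ± 1.77 CPM against 0 counts in naive lung, at least 92.9-fold higher, the aryl hydrocarbon receptor gene Ahr rose by 2.68 ± 0.52 and Irf4 by 2.59 ± 0.53. Il17a was at 9.38 ± 9.83 CPM and 2 counts in naive lung and was not called. Klrb1b was the 1 of 22 ILC1 and natural killer genes to rise (4 ± 0.76), with 2 higher over the list alone and 1 with either library left out. Cytokine receptors had 3 of 25 higher and 2 lower, the same over the list alone, and 3 higher and 1 lower with either library left out. Il2rb (2.54 ± 0.48) and Tnfrsf1b (2.78 ± 0.52) were the other genes higher.

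Immediate early and stress genes were higher in 8 of 30 cases and lower in 1, with 10 and 2 over the list alone, 4 and 2 without intestinal replicate 1, and 9 and 0 without replicate 2. The heat shock genes Hspa1a and Hspa1b, near-identical copies whose counts are uncertain, were at 1160 ± 351 and 800 ± 420 CPM against 21.9 and 9.3, and Hsph1 (3.89 ± 0.46, adjusted p = 1.05e-09) and Dnajb1 (4.17 ± 0.50, adjusted p = 7.86e-09) were higher too. Nr4a3 was at 3980 ± 2400 against 879 CPM (2.03 ± 0.44 [1.38, 2.69], and adjusted p = 0.154 without replicate 1). Residency genes were higher in 5 of 15 cases and lower in 1, with 7 and 1 over the list alone, and 2 were higher with either library left out, with 1 and 0 lower. Prdm1 was among those higher (2.37 ± 0.56, and 2.06, adjusted p = 0.0628 without replicate 1).

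Cell division genes were higher in 3 of 40 cases, with 5 over the list alone, and in 5 and 0 cases without intestinal replicates 1 and 2. Mki67 was at 149 and 834 CPM in the 2 intestinal libraries against 91.1 in naive lung (1.95 ± 0.44 [3.19, 0.71], and adjusted p = 1 without replicate 2). In cholesterol synthesis 2 of 22 genes were higher, Idi1 (3.30 ± 0.78, and 3.04, adjusted p = 0.0722 without replicate 2) and Cyp51 (2.05 ± 0.54, and 1.84, adjusted p = 0.106 without replicate 1), with 4 over the list alone and 1 with either library left out, and 0 were lower. Of 25 interferon response genes Gbp3 was higher (3.74 ± 0.81, and 3.23, adjusted p = 0.0513 without replicate 2), and of 24 costimulatory and checkpoint receptors Ctla4 was higher (1.75 ± 0.49 [2.35, 1.14], and adjusted p = 0.753 without replicate 2), with 1 and 3 higher over the list alone. Of 19 neuropeptide and lipid receptors 2 were lower, with 4 over the list alone, Ramp1 (-6.15 ± 1.16 [at least 67.9-fold, -4.36], and adjusted p = 0.146 without replicate 2) and Alox5 (-2.93 ± 0.66 [-3.94, -1.93], and adjusted p = 0.497 without replicate 2). Glycolysis had 0 of 22 genes called, over all genes or over the list alone.

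Of 21 genes of S1P sensing and egress 0 were called, over all genes, over the list alone, or with either intestinal library left out. S1pr1 was at 8.34 ± 1.36 and 8.42 CPM (-0.02 ± 0.68), S1pr4 at 3.37 ± 3.05 and 10.9 (-1.90 ± 0.92), Klf2 at 26.1 ± 8.26 and 3.84 (2.63 ± 1.14) and Cd69 at 203 ± 165 and 250 (-0.59 ± 0.51). Itga4 was at 1900 ± 651 and 1920 CPM (-0.06 ± 0.43).

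Intestinal epithelial markers were higher in 9 of 18 cases, with 14 over the list alone, 11 without intestinal replicate 1 and 3 without replicate 2. The sucrase Sis was at 884 CPM in replicate 2 and 10.8 in replicate 1, and Muc2, the goblet cell mucin, at 1190 and 3.16. Of 16 macrophage markers 3 were lower, Chil3 (-8.62 ± 0.56 [at least 261-fold, -7.37], adjusted p = 4.74e-45), Lyz2 (-5.29 ± 0.53) and Mrc1 (-4.63 ± 0.62 [ratio 0.00308 to 0.044, -3.56]), with 7 over the list alone, 4 without replicate 1 and 3 without replicate 2. Granulocyte and mast cell markers had 3 of 11 lower, also over the list alone, such as Ear1 (1 count over both intestinal libraries, ratio interval 0.000222 to 0.0503), and 2 without replicate 2. Scgb1a1 was the 1 lower of 8 lung epithelial markers, also over the list alone (at least 34.5-fold lower [13.6, 20.9]). Of 13 B and plasma cell markers 2 were higher, over all genes, over the list alone and with either library left out, Cd79b and the immunoglobulin joining chain Jchain, at 195 ± 65.9 against 7.83 CPM (4.54 ± 0.74). Of 15 T cell markers 2 were lower, also over the list alone, and 0 with either library left out. Of 15 stromal and endothelial markers 2 were higher, with 3 over the list alone, while without replicate 2 the calls were 0 higher and 1 lower. Erythroid or platelet (4) and sex-linked genes (3) had 0 calls.

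In total 277 genes were higher and 101 lower in the intestine, and 1338 had an unadjusted p under 0.05. Without intestinal replicate 1 the count was 385, of which 299 were shared, and without replicate 2 it was 198, of which 183 were shared. The genes with the largest called rise included markers of gut epithelium found in replicate 2, such as Lypd8, at 4390 CPM there and 101 in replicate 1, Apob (917 and 23.2) and Dmbt1 (952 and 12.6). High in both were the lipid flippase gene Atp8a2 (102 CPM in replicate 2 and 178 in replicate 1) and the connexin Gjb2 (208 and 173). Lower in the intestine were genes such as the adhesion gene Flrt2 (-5.73 ± 0.87). By size alone, 589 genes were higher and 512 lower, 1101 in all, against 1861 without intestinal replicate 1 and 764 without replicate 2. With at least 10 CPM in some library required, 190 genes were called.

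IL-25 lung ILC2s were next set against naive intestinal ILC2s, since the series concerns traffic of such cells between organs. S1P receptor genes were higher in IL-25 lung: S1pr1 was at 225 against 8.34 ± 1.36 CPM (4.71 ± 0.66, adjusted p = 3.28e-10) and S1pr4 at 107 against 3.37 ± 3.05 (5.15 ± 0.90 [ratio 30 to 427, 4.19], adjusted p = 5.74e-06). Ccr9 was at 2180 against 263 ± 77 CPM (3.08 ± 0.46, adjusted p = 1.54e-09) and Ctla4 at 2200 against 66.8 ± 37.8 (5.16 ± 0.48 [4.55, 5.77], adjusted p = 3.41e-21). Il5 (-5.40 ± 0.47, adjusted p = 8.62e-15), Csf2 (-7.10 ± 0.63 [-6.46, -7.74], adjusted p = 4.69e-15), Il1rl1 (-3.52 ± 0.45, adjusted p = 1.86e-08) and Gata3 (-2.73 ± 0.46, adjusted p = 2.49e-05) were lower in IL-25 lung.

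Of 21 genes of S1P sensing and egress 5 were higher and 0 lower, also over the list alone, and 5 and 4 were higher without intestinal replicates 1 and 2. The list included Msn (2.36 ± 0.44) and Gnai2 (2.08 ± 0.52, and 1.56, adjusted p = 0.18 without replicate 1), and its median was 1.23, or 0.95 with the 1 gene at 0 set to its limit. Cdh5 was at 249 against 3.84 ± 5.44 CPM (7.25 ± 0.75 [4.96, at least 315-fold], adjusted p = 2.39e-12), and the ratio of S1pr1 to Cdh5 was 0.902 in IL-25 lung and 1.21 in intestinal replicate 2, with 0 counts of Cdh5 in replicate 1. Klf2 was at 35.2 and 26.1 ± 8.26 CPM (0.46 ± 1.11) and Cd69 at 430 and 203 ± 165 (1.37 ± 0.51).

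Homing genes were higher in 5 of 29 cases and lower in 5, with 6 and 5 over the list alone, 5 and 4 without intestinal replicate 1, and 3 and 5 without replicate 2. Ccr4 (-3.41 ± 0.47), Ccr8 (-3.73 ± 0.61 [-2.75, -4.71]) and Cxcr6 (-2.38 ± 0.51) were lower. Itga4 was at 7020 against 1900 ± 651 CPM (1.93 ± 0.43, and 1.57, adjusted p = 0.068 without replicate 2), and Itgb7 at 378 against 90 ± 17.4 (2.08 ± 0.54, and 1.88, adjusted p = 0.107 without replicate 2). Residency genes were higher in 1 of 15 cases (Prdm1, 2.78 ± 0.55) and lower in 5, with 2 and 8 over the list alone, 2 and 5 without replicate 1, and 1 and 7 without replicate 2, including Rgs2 (-3.48 ± 0.44) and Inpp4b (-3.22 ± 0.45).

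Identity genes were higher in 1 of 26 cases and lower in 11, also over the list alone, with 10 lower with either library left out, among them Rora (-3 ± 0.43), Il17rb (-2.26 ± 0.48), Il7r (-3.05 ± 0.44), Kit (-2.16 ± 0.47) and Arg1 (-2.20 ± 0.47). Thy1 was the gene higher (2.09 ± 0.61 [2.75, 1.43], and adjusted p = 0.48 without replicate 2), and Klrg1 was at 343 and 195 ± 27.2 CPM (0.82 ± 0.55). Cytokine receptors had 0 of 25 higher and 5 lower, over all genes and with either library left out, and 1 and 6 over the list alone. Effector genes were higher in 1 of 24 cases and lower in 11, over all genes and with either library left out, and 4 and 11 over the list alone. Calca (-6.30 ± 0.53) and Areg (-1.79 ± 0.49) were lower with Il5 and Csf2. Il13 was at 1050 and 488 ± 248 CPM and was not called (1.20 ± 0.49, adjusted p = 0.187). The macrophage and dendritic cell chemokine Ccl17 was higher (at least 54.7-fold higher [21.6, 33.1]).

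Cell division genes were higher in 21 of 40 cases and lower in 0, with 32 and 1 over the list alone, and higher in 11 and 22 cases without intestinal replicates 1 and 2. Examples were Mki67 (3.31 ± 0.44 [2.07, 4.55]) and Rrm2 (5.62 ± 0.61). Glycolysis had 2 of 22 genes higher, also over the list alone, and 0 and 3 without replicates 1 and 2, Gapdh being at 2920 against 850 ± 219 CPM (1.81 ± 0.44, and 1.54, adjusted p = 0.077 without replicate 1). Immediate early and stress genes were higher in 1 of 30 cases and lower in 11, with 1 and 12 over the list alone, 0 and 9 without replicate 1, and 1 and 12 without replicate 2. Nr4a3 (-4.73 ± 0.44 [-4.07, -5.39]) and Fosl2 (-2.97 ± 0.44) were among the lower, and the cytokine signalling inhibitor Socs3 was the gene higher (4.20 ± 1.05 [2.95, 5.45], and adjusted p = 0.244 without replicate 1). Costimulatory and checkpoint receptors were higher in 3 of 24 cases and lower in 7, with 3 and 9 over the list alone, 3 and 7 without replicate 1, and 1 and 8 without replicate 2, such as Cd96 (-3.62 ± 0.55) and Tnfrsf18 (-3.93 ± 0.72) on the lower side.

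Neuropeptide and lipid receptors were higher in 1 of 19 cases and lower in 3, with 3 and 4 over the list alone, 0 and 2 without replicate 1 and 0 and 3 without replicate 2, Vipr2 being among the lower (-3.14 ± 0.57). Il22 had 0 counts in IL-25 lung, at least 124-fold lower, as the 1 called type 17 gene of 19, with 3 lower over the list alone and 1 and 2 without replicates 1 and 2. Of 22 ILC1 and natural killer genes Gzma was higher (3.68 ± 1.05 [2.94, 4.43], and adjusted p = 0.248 without replicate 1) and Ifng lower (at least 111-fold lower [66.9, 139]), with 2 and 2 over the list alone. Cholesterol synthesis (22) and interferon response (25) had 0 calls, over all genes or over each list alone.

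Macrophage markers were higher in IL-25 lung for 7 of 16 genes, also over the list alone, and for 6 and 3 without intestinal replicates 1 and 2, including Chil3 (10.95 ± 0.56 [at least 1310-fold, 9.70], adjusted p = 1.31e-67) and Lyz2 (6.71 ± 0.53). Stromal and endothelial markers were higher in 3 of 15 cases, with 5 higher and 1 lower over the list alone and 4 and 3 higher without replicates 1 and 2, including Vwf (6.80 ± 0.94 [ratio 73.2 to 2190, 6.05]) and Lyve1 (5.30 ± 0.69 [3.73, 6.86]). Intestinal epithelial markers were lower in 11 of 18 cases, with 15 over the list alone, 12 without replicate 1 and 3 without replicate 2. Lung epithelial markers were higher in 2 of 8 cases, with 3 over the list alone and 1 with either library left out, and granulocyte markers in 2 of 11, Ear1 and Ear2, in each case. Of 15 T cell markers the transcription factor Lef1 was higher (4.04 ± 0.92) in each case, and of 13 B and plasma cell markers 1 was higher and Jchain lower (-4.33 ± 0.73), with 0 higher with either library left out. Xist, the X inactivation transcript, was lower, at 5570 against 17700 ± 4620 CPM (-1.64 ± 0.42, and -1.37, adjusted p = 0.07 without replicate 1), and of erythroid or platelet genes (4) 0 were called.

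In total 454 genes were higher and 438 lower in IL-25 lung, and 2141 had an unadjusted p under 0.05. Without intestinal replicates 1 and 2 the counts were 651 (272 higher and 379 lower, 583 shared) and 638 (282 and 356, 557 shared). Tnfrsf8 had 0 counts in both intestinal libraries (at least 134-fold higher [52.7, 81]), as had the separase gene Espl1 (at least 89.9-fold higher [35.5, 54.4]). By size alone, 1108 genes were higher and 696 lower. DESeq2, with its own scaling, called 338 higher and 499 lower.

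ILC2s of the mesenteric node, which drains the gut, were set against naive intestinal ILC2s in the same way. S1pr1 was higher in the node, at 275 against 8.34 ± 1.36 CPM (4.99 ± 0.66, adjusted p = 1.55e-11), as were S1pr4 (5.20 ± 0.90 [ratio 31.1 to 444, 4.24], adjusted p = 3.24e-06) and Ccr9 (3.17 ± 0.46, adjusted p = 3.05e-10). Cd69 was lower, at 36 against 203 ± 165 CPM (-2.20 ± 0.52 [-1.26, -3.14], adjusted p = 0.000653, and adjusted p = 0.268 without replicate 1). The effector genes Il5 (-7.46 ± 0.49, adjusted p = 5.02e-23) and Areg (-7.51 ± 0.57, adjusted p = 2.41e-21) were lower.

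Of 21 genes of S1P sensing and egress 5 were higher and 1 lower, with 6 and 1 over the list alone, 4 and 0 without intestinal replicate 1, and 4 and 1 without replicate 2. Cdh5 was at 3.27 CPM in the node and 3.84 ± 5.44 in the intestine, and the ratio of S1pr1 to Cdh5 was 84.1 in the node. Klf2 was at 33 and 26.1 ± 8.26 CPM (0.37 ± 1.11). Homing genes were higher in 6 of 29 cases and lower in 7, with 6 and 8 over the list alone, 5 and 6 without replicate 1, and 3 and 7 without replicate 2. Ccr8 (-4.96 ± 0.63 [-3.98, -5.93]), Cxcr6 (-2.75 ± 0.51) and Gpr183, an oxysterol receptor (-3.23 ± 0.54), were lower. Ccr7 was at 44.4 and 6.86 ± 0.0197 CPM (2.64 ± 1.35).

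Immediate early and stress genes were lower in 22 of 30 cases and higher in 0, with 25 lower over the list alone and 19 and 22 without intestinal replicates 1 and 2, at a median of -3.36. Nr4a3 was at 7 against 3980 ± 2400 CPM (-8.94 ± 0.46 [-8.28, -9.59], adjusted p = 1.67e-33), and Fosl2 (-7.82 ± 0.45), Nr4a1 (-6.82 ± 0.48 [-5.96, -7.67]) and Atf3 (3 counts in the node, ratio interval 0.000227 to 0.00323) were lower too. Residency genes were higher in 1 of 15 cases and lower in 11, also over the list alone, with 1 and 10 without replicate 1 and 0 and 10 without replicate 2, including Rgs1 (-4.43 ± 0.51), Rgs2 (-7.33 ± 0.45) and Inpp4b (-2.79 ± 0.45).

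Effector genes were lower in 13 of 24 cases and higher in 2, with 14 and 2 over the list alone, and 12 and 0 with either library left out. Calca had 2 counts in the node against 709 ± 63.8 CPM in the intestine (ratio interval 3.93e-05 to 0.00117). Il13 was at 159 against 488 ± 248 CPM (-1.52 ± 0.49, -0.97, adjusted p = 0.427 without replicate 1 and -2.06, adjusted p = 0.00886 without replicate 2). Identity genes were higher in 1 of 26 cases and lower in 12, with 1 and 15 over the list alone, and 10 lower with either library left out, such as Rora (-4.34 ± 0.43), Gata3 (-3.43 ± 0.47), Il1rl1 (-4.84 ± 0.45), Il17rb (-2.18 ± 0.48) and Kit (-3.27 ± 0.47). Klrg1 was at 221 and 195 ± 27.2 CPM (0.18 ± 0.56). Cytokine receptors had 6 of 25 lower and 0 higher, with 2 higher and 11 lower over the list alone, and 7 and 6 lower without replicates 1 and 2, Il7r (-3.71 ± 0.44) and Il2ra (-3.40 ± 0.45) being among them.

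Cell division genes were higher in 31 of 40 cases and lower in 0, with 35 and 1 over the list alone, and higher in 18 and 30 cases without intestinal replicates 1 and 2. Mki67 was at 4930 against 492 ± 484 CPM (3.80 ± 0.44 [2.56, 5.04], adjusted p = 1.69e-12), and Top2a (3.67 ± 0.50 [2.23, 5.12]) and Rrm2 (6.04 ± 0.61) rose with it. Glycolysis had 3 of 22 genes higher and 0 lower, over all genes, over the list alone and without replicate 1, and 5 without replicate 2, such as Pkm (2.33 ± 0.54). Costimulatory and checkpoint receptors were higher in 2 of 24 cases and lower in 8, with 2 and 11 over the list alone, 1 and 7 without replicate 1, and 1 and 8 without replicate 2, including Cd274, the gene of PD-L1 (-2.55 ± 0.51), and Pdcd1lg2 (-3.99 ± 0.61) on the lower side. Neuropeptide and lipid receptors had 5 of 19 lower, with 7 over the list alone and 3 and 5 without replicates 1 and 2, among them Cysltr2, a leukotriene receptor (-3.10 ± 0.64).

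Type 17 genes were lower in 4 of 19 cases, with 4 over the list alone and 3 and 4 without replicates 1 and 2. Il22 had 0 counts in the node (at least 118-fold lower), and Ahr was lower (-2.29 ± 0.52). ILC1 and natural killer genes were higher in 1 of 22 cases and lower in 3, with 1 and 4 over the list alone, 0 and 2 without replicate 1, and 1 and 3 without replicate 2, Klrb1b being lower (-4.84 ± 0.77). Cyp51 of 22 cholesterol genes (-1.85 ± 0.54, and -1.65, adjusted p = 0.113 without replicate 1) and Oasl2 of 25 interferon genes (-3.44 ± 0.83) were lower, with the same counts over each list alone.

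B cell markers were higher in the node for 4 of 13 genes, with 8 over the list alone, 4 without intestinal replicate 1 and 0 without replicate 2, such as Ms4a1, the gene of CD20, at 42.9 against 1.19 ± 1.68 CPM (5.5 ± 1.53 [at least 35.4-fold, 4], and adjusted p = 0.313 without replicate 2). Jchain was lower (-3.94 ± 0.72). T cell markers were higher in 3 of 15 cases, with 4 over the list alone and 1 and 2 without replicates 1 and 2, including Lef1 (4.63 ± 0.92). Intestinal epithelial markers were lower in 13 of 18 cases, with 15 over the list alone, 14 without replicate 1 and 4 without replicate 2, and stromal and endothelial markers in 5 of 15, with 6 over the list alone and 5 without replicate 1, against 1 higher and 0 lower without replicate 2. Chil3 was the 1 of 16 macrophage markers to be higher (3.83 ± 0.57 [at least 9.13-fold, 2.57]), in each case. Xist was lower, at 5490 against 17700 ± 4620 CPM (-1.66 ± 0.42, and -1.39, adjusted p = 0.0629 without replicate 1). Granulocyte (11), lung epithelial (8) and erythroid or platelet genes (4) had 0 calls, over all genes or over each list alone.

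In total 453 genes were higher and 685 lower in the node, and 2527 had an unadjusted p under 0.05. With an assumed coefficient of variation of 0.4 the calls were 2116 higher and 1912 lower. Without intestinal replicates 1 and 2 the counts were 922, of which 823 were shared, and 747, of which 705 were shared. Uhrf1, a regulator of DNA methylation (7.35 ± 0.72 [6.44, ratio 149 to 2120]), the phosphatase Cdc25b (7.13 ± 1.03) and Tnfrsf8 (at least 143-fold higher [56.3, 86.5]) were among the largest rises, and the immunoglobulin-like receptor gene Lilr4b (-9.92 ± 0.49) and the transglutaminase Tgm2 (-8.80 ± 0.66) among the largest falls. By size alone, 1164 genes were higher and 1011 lower. DESeq2, with its own scaling, called 352 higher and 839 lower.

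**Figure D3:**
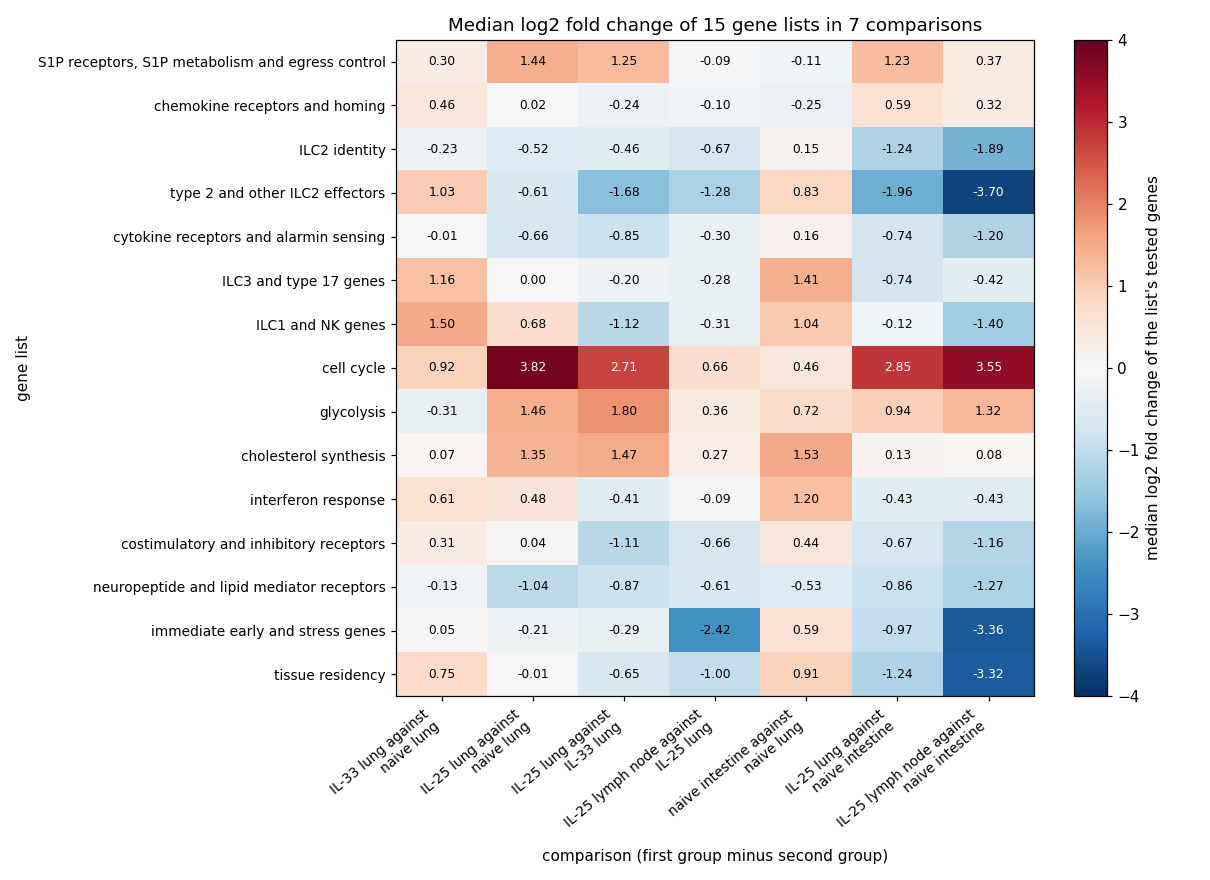
Median fitted log2 fold change of 15 gene lists (vertical axis) in the 7 comparisons (horizontal axis). The cell cycle list was at 3.82 in IL-25 lung against naive lung, and the immediate early list at -2.42 in the node against IL-25 lung.

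As a description with no test, each treated library was placed between naive lung and naive intestine over the 378 genes called between those tissues. In IL-25 lung 31.5% of these genes lay nearer the intestinal level, in IL-33 lung 27.2% and in the lymph node 33.1%. The range with either intestinal library alone was 29.6% to 33.6% for IL-25 lung, 24.3% to 29.9% for IL-33 lung and 31.2% to 37.3% for the node. For the 277 genes higher in the intestine the share was 29.6% in IL-25 lung, 33.2% in IL-33 lung and 19.9% in the node, and for the 101 genes lower in the intestine it was 36.6%, 10.9% and 69.3%.

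In assembly GRCm38, S1pr1 lies on chromosome 3 at 115710433 to 115715072 and S1pr4 on chromosome 10 at 81497747 to 81500132.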

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

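No paired analysis was possible because the groups share only replicate number 1. The spread rests on 1 residual degree of freedom from the intestinal pair, and each lone sample was assumed to vary like the others. Under that assumption the simulation recovered 5.3% of 4-fold changes between lone libraries with 3.4% false calls, and 2.7% with 26.4% where spread differed between genes. Real false-call rates are unknown. A gene not called may still differ by that much. The fits without an intestinal replicate that carry over dispersions were chosen after seeing the data, as were the shares nearer the intestine over the genes they call.

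Counts of called genes for the 7 comparisons, in the order of the report, were 163, 409, 523, 160, 378, 892 and 1138. They stayed within 1.5 times these under RLE scaling, with no filter, with the effective length offset, with DESeq2 (211, 457, 660, 149, 392, 837 and 1191) and, for the 3 comparisons with intestine, with only the 2 groups compared. DESeq2 called 338 higher and 499 lower in IL-25 lung against intestine, where edgeR called 454 and 438. With limma-trend the count was 0 in all 7, and 1352, 1299, 1971, 657, 1169, 1885 and 2026 genes had an unadjusted p under 0.05, so the calls rest on the count-based tools. With an assumed coefficient of variation of 0.4 the counts were 2599, 1857, 3677, 828, 2223, 3388 and 4028, and with 0.2 they were 6096, 5785, 7715, 1746, 5360, 7312 and 7688, as a smaller assumed spread gives more calls. The balance of directions turned in 3 comparisons, as given in the report for 0.4: at 0.2 it was 2751 higher and 3345 lower for IL-33 against naive lung, 4566 and 3149 for IL-25 against IL-33 lung, and 3978 and 3710 for the node against intestine. With at least 10 CPM in some library they were 18, 166, 263, 89 and 190 for the first 5, and 643 and 866 for the last 2, with fewer genes tested. The cause was not tested beyond that.

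Leaving out an intestinal library gave 198 to 385 calls for intestine against lung, 638 to 651 for IL-25 lung against intestine and 747 to 922 for the node against intestine, the lower value without replicate 2 each time. Genes differing by size numbered 1861 without replicate 1 and 764 without replicate 2 for intestine against lung. Under RLE, TPM and the prior count of 0.5 the size counts stayed within 1.5 times in all 7.

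On TPM the median fold of all genes shifted by -0.61, -0.34, 0.28, -0.03, -0.63, 0.3 and 0.28 in the 7 comparisons, and by at most 0.08 under RLE. For intestine against lung, TPM turned the medians of the costimulatory list to -0.16 and the immediate early list to -0.08, and without replicate 2 the glycolysis median was -0.08, with 1.21 without replicate 1. The cause was not tested. Of 168 list medians, RLE moved 0 beyond its limit, TPM 71 and the prior count 15. Without replicate 1, 24 of 72 moved, and without replicate 2, 35. Of 328 values of named genes, RLE brought 2 past the threshold, TPM moved 91 and the prior count 74, and 45 of 140 moved with either replicate left out. No called named gene changed sign.

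Over the 385 genes called without replicate 1, shares nearer the intestine were 26.2%, 29.9% and 28.3% for IL-33 lung, IL-25 lung and the node. Over the 198 called without replicate 2 they were 23.2%, 26.8% and 33.3%.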

Other observations

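4 genes named in the comparisons are given here over all 6 libraries. Stab2 was at 2350 CPM in naive lung, 761 in IL-33 lung, 19.7 in IL-25 lung, 10.5 in the node and 417 ± 241 in the intestine. Tox2 was at 114 and 68.8 CPM in the 2 IL-25 libraries and at 5.44 or less in the other 4. Dtx1, a Notch pathway gene, was at 60.8 and 83.6 CPM in the IL-25 libraries and 31.9 ± 0.414 in the intestine, with 1.01 in IL-33 lung and 0 counts in naive lung. Tnfrsf8, the gene of CD30, was at 64 and 68.4 CPM in the IL-25 libraries and had 2 counts over the other 4. Y-linked genes had 4 to 16 counts per library and Xist was at 5490 to 21000 CPM, as in female cells, in all 6.

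The tests on endothelial RNA, on macrophage and epithelial RNA, and on depth, dissociation and activation in the node were chosen after the result was seen, with their bounds, and the test of the position between lung and intestine before.

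S1pr1 in the lung libraries rose with endothelial RNA. Over the 3 lung libraries S1pr1 ranged 26.7-fold, while its ratio to Cdh5 ranged 1.99-fold, within the 4-fold bound set for endothelial RNA as the source. The values are consistent with S1pr1 of contaminating endothelium, and S1pr1 of the ILC2s themselves was not separated from it. In the node the ratio was 93.2 times that of IL-25 lung, past the 4-fold bound, arguing against endothelium with the lung ratio. T and B cells, whose markers summed to 604 and 616 CPM in the node, could be another source and were not tested.

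Immediate early genes were low in the node. Lower depth does not account for this: in the 4 libraries with fewer counts than the node the list lay above it by a median log2 difference of 2.6 or more. The effector median against IL-25 lung was -1.28, or -1.01 with the 1 gene at 0 set to its limit, the direction that lower activation needs, while the cell cycle list had a median of 0.66, with 0 of 40 genes called. Markers of macrophages (median -2.56, summing to 70 against 2770 CPM) and of stroma and endothelium (-3.04, or -2.97 with genes at 0 set to their limits) were lower in the node too, so RNA of such cells could account for a part of the immediate early and effector RNA of the lung library. That was not tested. Less stress from tissue dissociation stays open, as 2 of 4 heat shock genes were at least 2-fold lower in the node (Hspa1a -2.87, Hspa1b -1.95, Hsph1 0.4, Dnajb1 -0.02). The organs could differ in several of these ways at once, and the cells of the 2 libraries carry different labels too.

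IL-25 lung cells did not hold the intestinal expression pattern as a whole: 31.5% of the 378 genes called between the tissues lay nearer the intestine, where over 50% had been required. Those calls include epithelial genes of intestinal replicate 2, and 183 of the 378 were also called without it. Over the 198 genes called without replicate 2, set against replicate 1 in a fit chosen after seeing the data, the share was 26.8%. The share that a second naive lung library would give is not known here. The value does not bear on where the cells came from, since treatment itself may change these genes.

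Tests on 2 further patterns were run, and after their values had been seen these patterns were left unweighed to keep to 3, so they are given as values alone. In IL-33 lung the macrophage list without Chil3 had a median of 2 against naive lung, and the ratio of Chil3 to Lyz2 was 1.08 in naive lung, 13.9 in IL-33 lung and 2.03 in IL-25 lung. In intestinal replicate 2 the 18 epithelial markers had a median log2 difference of 5.4 from replicate 1.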
